A study of Mus musculus with 8 samples.

How the data were processed

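The series holds 8 Affymetrix arrays of liver RNA from male C57BL/6 mice, 2 arrays for each of 4 groups (wild type and Tob1 null, at 0 h and 24 h after partial hepatectomy), and each array was hybridised with a different pool of 3 animals. The deposited values are in log2 units, as read from the values themselves. Apart from high values, which were not checked, 2 to the power of each value falls on steps of 0.01 within rounding. On the linear scale 894 to 1275 values per array equal 1, with at most 3 below it. The arrays appear to have been scaled before deposit, as the 2% trimmed mean on the linear scale lies between 95.9 and 99.9 in every array. The algorithm that made the signals is not given in the sources used here. Of 45101 probe sets, 64 controls were left out.

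The 25th, 50th and 75th percentiles differed between arrays by 0.62, 0.38 and 0.17, beyond the tolerance of 0.1 set before the data were examined, so the values were quantile normalised between arrays. A probe set was kept if it lay above the 40th percentile of its array in at least 2 of the 8 arrays (a limit of 3.60 on the normalised scale). Among probe sets with exactly 1 gene symbol, the one with the highest mean over the arrays stood for the gene, which left 14450 genes. Probe sets with no symbol or with several were tested apart. The annotation at hand does not name the genome build of the array, so no coordinates are given.

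A linear model with a mean for each of the 4 groups was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (4 residual and 2.01 prior degrees of freedom). The comparisons were 24 h against 0 h in each genotype, null-labelled against wild type at each time, the difference between the responses, and the genotype difference averaged over both times. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided. The words rose and fell are used of genes and lists that passed. The number of arrays limits the precision of every value. Fits that leave out an array leave 1 array in its group, which is then assumed to vary like those of the other groups.

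Before the data were examined, 35 gene lists (pathways and markers of cell types) were fixed and tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were the alternatives. No list passed with an estimated correlation in any comparison, while fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, passed 10, 13, 1, 0, 1 and 0 lists in the order of comparisons given above. The DNA replication list was among the 35, but giving it the lead was decided after the list results were seen.

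Genes were named by a rule fixed before the data were examined. It takes the 8 largest rises and the 8 largest falls among genes that passed and whose groups do not overlap. Where fewer than 4 passed in a direction, it takes the 4 with the smallest p. It adds up to 4 members of each list described, those with the smallest p, and always Tob1, Tob2, Btg1, Btg2, Cnot7, Cdk1, Ccna2, Ccnb1, Ccnd1 and Ccne1 where measured; Ccnb1 was not analysed here. Predicted genes were skipped. Values of the always named genes that did not pass are given only in part.

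The alternatives were the deposited values and median centring in place of quantile normalisation, no filter and a filter at the 60th percentile, other rules for choosing probe sets, a trended and robust prior, array weights, a replicate block, fits of only the 2 groups compared, other thresholds, and leaving out each array in turn. Damping of low values by adding 16 on the linear scale, and a crossed replicate block, were added after the data were seen. The procedure was tested on simulated data in which 200 genes were changed in 1 group. Of genes tested with a log2 change of 1 in it, 37.4% were called in the response and 5.1% in the difference between responses, and of those with a change of 2, 75.5% and 50.0%. Among unchanged genes 6 and 5 were called. The simulated noise was independent between genes and had no shifts of whole arrays, so these shares need not hold for the real arrays.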

Results

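Gene expression was measured on 8 Affymetrix mouse arrays hybridised with liver RNA from male C57BL/6 mice. The 4 groups were wild type and Tob1 null animals, each without surgery (0 h) and 24 h after partial hepatectomy, the removal of a large part of the liver that starts regrowth of the remaining lobes. Each group had 2 arrays, and each array carried the pooled RNA of 3 different animals, so the errors given below come from the spread between pools. The SE of a gene takes this spread over all 4 groups and is moderated toward that of other genes. Tob1 belongs to the BTG/TOB family of antiproliferative proteins, which bind the CCR4-NOT deadenylase, and the series title describes it as a repressor of liver regrowth; the comparisons below address how the hepatectomy response differs without it. Replicate arrays correlated at 0.951 to 0.959 over all probe sets. After filtering, 14450 genes were tested, with differences given as log2 ± SE for 2 arrays against 2, and the number of arrays limits the precision of every value. The signal ratio between 3' and 5' probe sets, a sign of RNA quality, was highest in the null-labelled arrays at 0 h for both controls. For actin it was 1.57 ± 0.03 on the log2 scale (SD, n = 2) there and 1.22 ± 0.25 in wild type at 0 h. At 24 h it was 0.97 ± 0.09 in wild type and 1.27 ± 0.07 in the null-labelled arrays. For Gapdh the ratios in the same order were 0.52 ± 0.02, 0.23 ± 0.07, 0.07 ± 0.10 and 0.16 ± 0.12.

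The probe sets of the targeted gene, Tob1, differed between the genotypes in opposite directions, and none passed the threshold. The brighter of its probe sets stands for the gene in all comparisons. It read 11.07 ± 0.05 (SD, n = 2) in the arrays labelled Tob1 null and 10.50 ± 0.05 in wild type at 0 h. At 24 h it read 10.62 ± 0.06 against 10.03 ± 0.24. In a limma fit of all probe sets the difference was 0.57 ± 0.18 at 0 h (adjusted p = 0.564) and 0.59 ± 0.18 at 24 h (adjusted p = 0.523). In the fit of genes, used in the comparisons below, the adjusted p values for it were 0.403 and 0.272, so it did not pass in either. A dimmer second probe set read 3.35 ± 1.0 against 4.61 ± 0.83 at 0 h and 3.31 ± 0.74 against 4.61 ± 0.49 at 24 h. In the fit of probe sets its differences went in the other direction, -1.25 (adjusted p = 0.728) and -1.31 (adjusted p = 0.695). Whether either probe set lies in the deleted part of the gene is not known here, and a probe set outside it checks nothing. The groups are therefore called wild type and null-labelled below, and every direction between genotypes rests on the labels alone.

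In wild type liver, acute phase, proteasome and ribosome biogenesis genes and regulators of the G1 to S step were higher as groups 24 h after hepatectomy. Genes of drug, bile acid and amino acid metabolism were lower. These calls are by camera with the preset correlation, and none held with an estimated correlation (smallest adjusted p = 0.427). No group held sham-operated animals. Here and below, effects of the operation and of the loss of liver therefore cannot be told apart. The mean 3' to 5' ratio was also lower at 24 h (24 h minus 0 h ± SE, actin -0.25 ± 0.14, Gapdh -0.16 ± 0.09). G2 and mitosis genes did not pass as a group (median -0.04, adjusted p = 0.974). Of the 14450 genes, 1331 passed the threshold, 597 higher and 734 lower, of which 289 and 384 differed at least 2-fold. The largest rises were in Lcn2 (7.58 ± 0.28, adjusted p = 0.00169), an iron-sequestering acute phase protein, Cidec (6.38 ± 0.74), a lipid droplet protein, and Saa2 (5.09 ± 0.30), a serum amyloid. Sult1e1, the oestrogen sulfotransferase, rose by 5.04, Apoa4 by 4.53, Mfsd2a by 4.25, Cgref1 by 4.16 and Tnfrsf12a, the TWEAK receptor, by 4.07. The largest falls were in the uridine phosphorylase Upp2, which fell by 5.78 ± 0.26 (adjusted p = 0.00277), and in Clec2h, which fell by 5.64. The steroid dehydrogenases Hsd3b5 and Hsd3b2 fell by 5.03 and 4.59, Abca8a by 4.45, Keg1 by 4.34, Cnmd by 4.06 and Serpinb1a by 3.99. Cidec, Sult1e1, Cgref1, Clec2h, Cnmd and Serpinb1a had a group mean below the filter limit of 3.60, where a fold is imprecise. Among the genes followed throughout, Ccnd1 (cyclin D1) rose by 2.00 ± 0.45 (adjusted p = 0.0496), and Tob1, Tob2, Btg1, Btg2, Cnot7, Cdk1, Ccna2 and Ccne1 did not pass. The count rests on few arrays: it was 7 without the first and 3 without the second wild type array at 0 h, and 26 without the first wild type array at 24 h. It was 333 and 343 without the first and the second null-labelled array at 0 h. Of the 1331 genes, 7, 3, 23, 319 and 330 respectively were still called in these fits. The count was 332 with a replicate block, 2592 with a trended and robust prior and 2 when only the 2 groups compared were fitted.

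Among the lists fixed in advance, the acute phase list rose most by its members. Of 26 measured acute phase genes, 11 rose and none fell (16 rose and 2 fell adjusted over the list alone), with a median of 0.71 (camera adjusted p = 1.87e-08, adjusted p = 0.427 with an estimated correlation). Orm2, an orosomucoid, rose by 3.59 and Apcs, serum amyloid P, by 2.04. All 31 proteasome genes were higher, with a median of 0.44 (adjusted p = 1.73e-10, adjusted p = 0.427 with an estimated correlation). Of these, 9 rose (19 adjusted over the list alone), among them Psmc4 by 0.94 and Psmd4 by 0.71. Ribosome biogenesis genes were higher in 31 of 32 cases, with a median of 0.66 (adjusted p = 2.21e-08, adjusted p = 0.583 with an estimated correlation). Of these, 6 rose (15 adjusted over the list alone), among them Ncl (nucleolin) by 1.14 and Nop58 by 1.88; the median was 0.40 without the first wild type array at 24 h. G1 to S regulators had a median of 0.56 (adjusted p = 0.000463, adjusted p = 0.507 with an estimated correlation), and 3 of 20 rose (8 adjusted over the list alone), namely Tfdp1 by 0.71, Cdk4 by 0.56 and Ccnd1. Fatty acid oxidation and lipid droplet genes had a median of 0.33 (adjusted p = 0.000786, adjusted p = 0.507 with an estimated correlation). Of the 30 measured, 6 rose (13 rose and 3 fell adjusted over the list alone), among them Ehhadh by 1.22, Cpt1a, the carnitine palmitoyltransferase of mitochondrial fatty acid import, by 0.80 and Acadl by 0.64. DNA replication genes had a median of 0.61 (adjusted p = 0.000786, adjusted p = 0.677 with an estimated correlation), but only 2 of 43, Mcm2 (2.43) and Mcm5 (2.42) of the replicative helicase, rose. Tk1, the thymidine kinase, fell by 2.67, and the list's call ended without the second wild type array at 24 h (median 0.36, adjusted p = 0.16). ER chaperones (0.32, adjusted p = 0.00931, adjusted p = 0.583 with an estimated correlation) passed as well, with Asns up by 2.03 and Manf by 0.91. They missed without the second wild type array at 24 h (median 0.29, adjusted p = 0.0765) and on the deposited values (median 0.22, adjusted p = 0.0653).

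The lists that fell in wild type liver were led by male-biased liver genes, with a median of -1.11 (adjusted p = 3.83e-07, adjusted p = 0.507 with an estimated correlation). Of 18, 10 fell (13 adjusted over the list alone), among them Cyp2u1 by 2.45 and the organic anion transporter Slco1a1 by 1.70. Of 38 cytochrome P450 and drug metabolism genes, 12 fell and 1 rose (19 and 4 adjusted over the list alone). The median was -0.65 (adjusted p = 3.72e-05, adjusted p = 0.507 with an estimated correlation) and -0.41 without the first wild type array at 24 h. Ces1d fell by 1.96 and Cyp2c55 by 2.31, while Cyp2b10, a target of the nuclear receptor CAR, rose by 1.36. Bile acid genes had a median of -0.66 (adjusted p = 4.09e-05, adjusted p = 0.507 with an estimated correlation), and 6 of 25 fell (13 adjusted over the list alone), including Akr1d1, a reductase of bile acid synthesis, by 2.69. Interferon response genes were lower in 23 of 24 cases with a median of -0.64 (adjusted p = 3.72e-05, adjusted p = 0.507 with an estimated correlation). Of these, 6 fell (11 adjusted over the list alone), for example Psmb8 by 1.35 and Rsad2 by 1.23. Urea cycle and amino acid genes had a median of -0.47 (adjusted p = 0.00508, adjusted p = 0.677 with an estimated correlation), with Haao down by 1.48 and Mat1a, which makes S-adenosylmethionine, up by 1.29. This last call ended without the first wild type array at 0 h (median -0.39, adjusted p = 0.068). Without either wild type array at 0 h only the acute phase list kept any called member, 2 and 1.

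In the null-labelled arrays, acute phase genes and members of the DNA replication list were among the largest rises after hepatectomy. The mean 3' to 5' ratio was lower at 24 h here too (24 h minus 0 h ± SE, actin -0.30 ± 0.14, Gapdh -0.37 ± 0.09). Of the 14450 genes, 2121 passed, 1076 higher and 1045 lower, with 515 and 407 differing at least 2-fold. Lcn2 (6.50 ± 0.28, adjusted p = 0.00522) and Saa2 (6.00 ± 0.30) rose most, followed by Cer1 (5.69), Sult1e1 (5.54) and Uhrf1 (5.39 ± 0.86, adjusted p = 0.0192), which maintains DNA methylation at replication. Il22ra1, the IL-22 receptor, rose by 4.72, Mcm5 by 4.45 and Ly6d by 4.33. Upp2 fell by 4.95 ± 0.26, Serpinb1a by 4.49, Lrp2bp by 4.24, Tmem139 by 4.18 and Naaladl2 by 3.88. Nr1d1, the clock repressor REV-ERBα, fell by 3.92, Abca8a by 3.92 and Socs2, a target of growth hormone signalling, by 3.67. Cer1, Sult1e1, Uhrf1, Il22ra1, Serpinb1a, Lrp2bp, Tmem139 and Naaladl2 had a group mean below the filter limit. Cdk1, the mitotic kinase, rose by 2.21 ± 0.48 (adjusted p = 0.0358), Ccnd1 stood at 1.54 (adjusted p = 0.0708), and Tob1, Tob2, Btg1, Btg2, Cnot7, Ccna2 and Ccne1 did not pass. The count was 33 and 30 without the first and the second null-labelled array at 0 h, 1271 and 510 without those at 24 h, and 971 and 960 without the wild type arrays at 0 h. The count was 903 with a replicate block, 3204 with a trended and robust prior and 0 when only the 2 groups compared were fitted. The even split of directions depends on the scaling: with median centring 1245 genes were higher and 469 lower, while the median over all genes moved to 0.12.

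DNA replication genes had a median of 1.52 in the null-labelled response (camera adjusted p = 9.11e-10, adjusted p = 0.445 with an estimated correlation). Of 43 measured, 22 rose and none fell (29 rose and 2 fell adjusted over the list alone). Examples were Pcna, the sliding clamp (1.60), Rrm2, the ribonucleotide reductase subunit (2.14), Orc6 of the origin recognition complex (1.82) and Mcm5. Without either null-labelled array at 0 h none of them was called singly, and 8 were without the first null-labelled array at 24 h, 13 and 12 without the wild type arrays at 0 h. G1 to S regulators (0.48, adjusted p = 0.00356, adjusted p = 0.461 with an estimated correlation) rose in 6 of 20 (9 adjusted over the list alone). Tfdp1 rose by 1.14, Skp2 by 1.55 and Ccne2 (cyclin E2) by 2.47. G2 and mitosis genes (0.38, adjusted p = 0.00356, adjusted p = 0.445 with an estimated correlation) rose in 9 of 43 (13 adjusted over the list alone). Mad2l1 rose by 2.53, Smc2 by 2.54 and Cks1b by 1.06. Both calls ended without the first null-labelled array at 24 h, where the medians were 0.31 (adjusted p = 0.0819) and 0.19 (adjusted p = 0.0876). Proteasome genes were again higher in all 31 cases, with a median of 0.47 (adjusted p = 1.66e-11, adjusted p = 0.445 with an estimated correlation), and 17 rose (26 adjusted over the list alone), led by Psmd14 (1.10). Of 26 acute phase genes, 10 rose (15 adjusted over the list alone; median 0.55, adjusted p = 3.34e-07, adjusted p = 0.445 with an estimated correlation), including Orm2 by 3.24. Ribosome biogenesis genes had a median of 0.49 (adjusted p = 0.000237, adjusted p = 0.603 with an estimated correlation), and 4 of 32 rose (0 adjusted over the list alone), among them Nhp2 by 1.19.

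On the falling side of the null-labelled response, male-biased liver genes had a median of -0.96 (adjusted p = 4.62e-06, adjusted p = 0.445 with an estimated correlation). Of 18, 11 fell (13 adjusted over the list alone), including Slco1a1 by 1.76 and Susd4 by 1.35. Bile acid genes (-0.72, adjusted p = 0.000154, adjusted p = 0.445 with an estimated correlation) fell in 9 of 25 (11 adjusted over the list alone), with Cyp8b1, the sterol 12-hydroxylase, down by 2.90. Fatty acid and triglyceride synthesis genes (-0.65, adjusted p = 0.000875, adjusted p = 0.445 with an estimated correlation) fell in 7 of 24 (10 adjusted over the list alone). Among them the lipogenic regulators Srebf1 and Mlxipl fell by 2.27 and 2.30, and Lpin1 by 2.86. Interferon response genes (-0.46, adjusted p = 0.00718, adjusted p = 0.57 with an estimated correlation) fell in 5 of 24 (9 adjusted over the list alone), among them Irf7 by 1.09. A further 3 lists passed but depended on single arrays: P450 genes (-0.51, adjusted p = 0.02, adjusted p = 0.598 with an estimated correlation), glucose metabolism (-0.38, adjusted p = 0.0203, adjusted p = 0.445 with an estimated correlation) and hepatocyte markers (-0.15, adjusted p = 0.0163, adjusted p = 0.445 with an estimated correlation). In these, Cyp2c23 fell by 1.49, the glycogen synthase Gys2 by 1.22 and Cebpa, a hepatocyte transcription factor, by 1.97. Without the second null-labelled array at 24 h their adjusted p values were 0.0905, 0.178 and 0.0596, at medians of -0.34, -0.27 and -0.16. The glucose list also missed the threshold without the first null-labelled array at 0 h (-0.31, adjusted p = 0.0521), and the hepatocyte list on the deposited values (-0.08, adjusted p = 0.108) and with median centring, where its median turned to 0.09 (adjusted p = 0.159). Of the lists that passed in wild type, fatty acid oxidation (median -0.02, adjusted p = 0.996), ER chaperones (0.16, adjusted p = 0.527) and urea cycle genes (-0.41, adjusted p = 0.0578) did not pass in the null-labelled response. The G2 and mitosis, fatty acid synthesis (-0.31, adjusted p = 0.162), glucose (-0.20, adjusted p = 0.6) and hepatocyte (-0.04, adjusted p = 0.304) lists in turn did not pass in wild type. The test of the difference between the responses itself gave adjusted p = 0.809 for the urea cycle, 0.0511 for glucose and 0.0511 for hepatocyte markers, and the other 4 of these lists passed it with the preset correlation only.

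**Figure D1:**
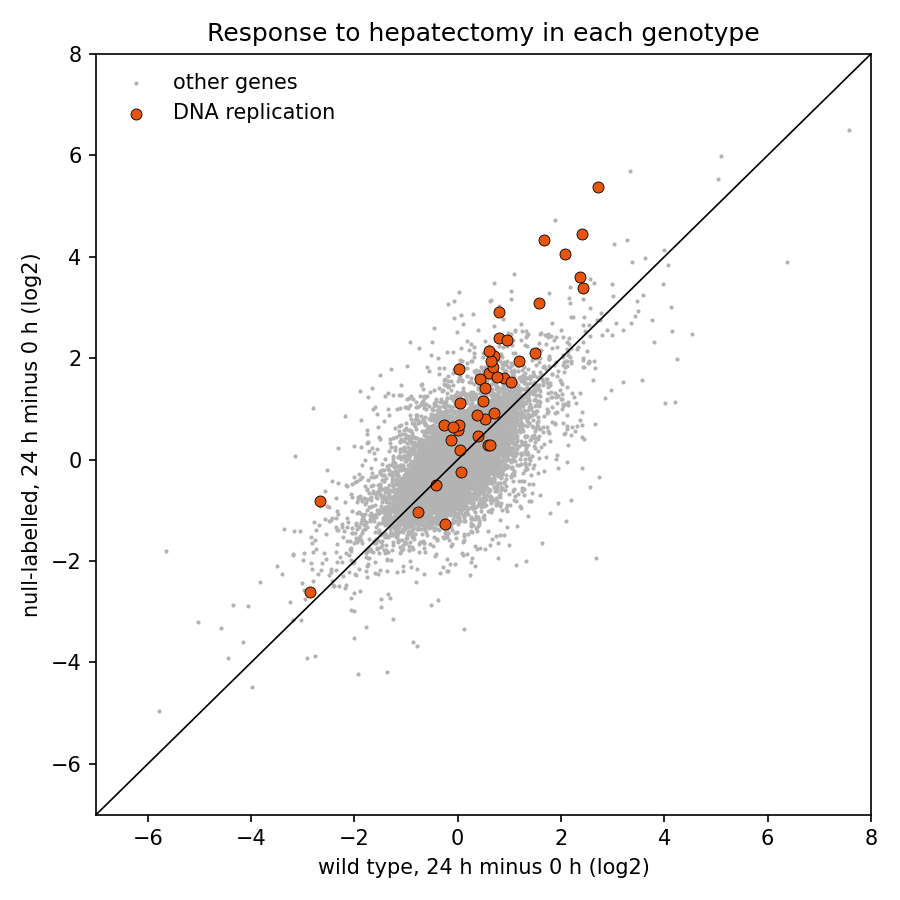
Difference 24 h minus 0 h (log2) of 14450 genes in wild type (horizontal axis) and in the null-labelled arrays (vertical axis), each a mean of 2 arrays minus a mean of 2, with the 43 measured DNA replication genes as filled orange points, all other genes in grey and a line of equal change. Across genes the Pearson r was 0.663, and the DNA replication genes have a median of 0.61 on the horizontal and 1.52 on the vertical axis.

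The responses of the 2 genotypes were alike across genes. Called genes that were higher in both numbered 397, where lists of these sizes drawn independently would share 44.5, and 470 were lower in both, where 53.1 would be shared. Both responses use the same variance of each gene, which by itself favours overlap, so these expected numbers are only a reference. Only 3 genes were called in opposite directions. Of the 2582 genes called in either response, 94.4% had the same sign in both. Across all genes, which are not independent replicates, Pearson's r was 0.663 and Spearman's rho 0.612. The 867 shared genes were 7 and 3 without the first and the second wild type array at 0 h, as only 7 and 3 genes were then called in wild type.

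Before surgery, no single gene passed between null-labelled and wild type liver with limma, although 1390 had an unadjusted p under 0.05 where 722 would by chance. Here and below, 722 is an average only. Genes are not independent, and how far such a count spreads by chance was not estimated. Other settings called from 0 to 13 genes, the most with a trended and robust prior. The genes with the smallest p that were higher in the null-labelled arrays were Prelid2 (below the filter limit in 1 group, 3.63 ± 0.31, adjusted p = 0.102), Dbp (2.15 ± 0.21, adjusted p = 0.125), a clock-driven transcription factor, Tmem51 (1.63) and Axin1 (1.21). Those with lower values were Igfbp1 (-2.60 ± 0.19, adjusted p = 0.0943), a secreted binding protein of insulin-like growth factors, Cystm1 (-1.97), Il22ra1 (-2.88) and Plb1 (-2.48), with Il22ra1 and Plb1 below the filter limit in 1 group. Of the genes followed throughout, Ccnd1 stood at 1.34 (adjusted p = 0.485), and Tob2, Btg1, Btg2, Cnot7, Cdk1, Ccna2 and Ccne1 did not pass either. ER chaperone and unfolded protein response genes were higher in 22 of 24 cases, with a median of 0.25 (camera adjusted p = 0.000285, adjusted p = 0.964 with an estimated correlation), including Ddit3 (1.12) and Dnajb9 (1.10). Endothelial markers were lower in 17 of 19 cases, with a median of -0.32 (adjusted p = 0.000285, adjusted p = 0.964 with an estimated correlation), including Pecam1 (-0.76) and Stab2 (-0.63). No member of either list passed over all genes, and 1 ER gene did adjusted over the list alone. These lists moved in the arrays with the highest 3' to 5' ratios (actin 1.57 against 1.22, Gapdh 0.52 against 0.23). The DNA replication list did not pass at 0 h (median -0.14, adjusted p = 0.198). Interferon, ribosome biogenesis, cholesterol synthesis, male-biased, Kupffer cell and cholangiocyte lists passed with all 8 arrays, at adjusted p values of 0.00493, 0.00821, 0.0138, 0.0159, 0.0109 and 0.0281 (adjusted p = 0.964 for each with an estimated correlation). Interferon and ribosome biogenesis genes were higher in the null-labelled arrays, and genes of the other lists named here were lower. The first null-labelled array at 0 h also stood apart from the rest by its female-biased liver genes (mean score 1.58 against -0.29 in the second), and without it the median of the male-biased list was -0.05. Each of these 6 lists lost its call when either of 2 arrays was left out. The adjusted p was 0.233 for interferon without the second wild type array at 0 h and 0.0599 without the first null-labelled one. Without the first wild type array at 0 h it was 0.186 for ribosome biogenesis, 0.189 for cholesterol synthesis, 0.112 for male-biased genes, 0.394 for Kupffer cell markers and 0.457 for cholangiocyte markers. Without the first null-labelled array at 0 h it was 0.163 for ribosome biogenesis, 0.391 for male-biased genes and 0.298 for cholangiocyte markers, and without the second 0.374 for cholesterol synthesis and 0.11 for Kupffer cell markers.

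At 24 h after hepatectomy, genes of DNA replication, mitosis and the interferon response were higher and fatty acid oxidation genes lower in the null-labelled arrays than in wild type, each as a group. The 3' to 5' ratio was also higher in the null-labelled arrays at 24 h (mean ± SD of 2 arrays, actin 1.27 ± 0.07 against 0.97 ± 0.09, Gapdh 0.16 ± 0.12 against 0.07 ± 0.10). The DNA replication list was higher in 38 of 43 genes, with a median of 0.68 (camera adjusted p = 2.21e-07, adjusted p = 0.819 with an estimated correlation). Its leading members were Rrm2 (1.45), Pcna (0.97), Rpa3 (1.19) and Orc6 (0.92), none of which passed over all genes, while 6 members did adjusted over the list alone. The list median was 0.37 without the first wild type array at 24 h, 0.28 without the first and 1.07 without the second null-labelled array. G2 and mitosis genes were higher in 35 of 43 (0.48, adjusted p = 3.26e-07, adjusted p = 0.819 with an estimated correlation). Kif4 stood at 1.14, Cks2 at 1.22 and Cdk1 at 2.45 (adjusted p = 0.218), and 9 passed adjusted over the list alone. The median was 0.31 without the first null-labelled array at 24 h. Interferon response genes were higher in 21 of 24 (0.34, adjusted p = 2.7e-06, adjusted p = 0.819 with an estimated correlation). Usp18 stood at 1.55 and Irf7 at 1.08, and 7 passed adjusted over the list alone. Its median was 0.17 without the first and 0.64 without the second wild type array at 24 h. Fatty acid oxidation and lipid droplet genes were lower in 25 of 30 (-0.31, adjusted p = 2.21e-07, adjusted p = 0.783 with an estimated correlation). Cpt1a stood at -1.66 (adjusted p = 0.0561), Vnn1 at -1.10 and the fatty acid translocase Cd36 at -0.99, and 3 passed adjusted over the list alone. A single gene passed over all genes, the glutathione transferase Gstm3 (2.58 ± 0.16, adjusted p = 0.0472), higher in both null-labelled arrays than in both wild type arrays, while 1695 genes had an unadjusted p under 0.05 where 722 would by chance. Leaving out any of the 8 arrays ended its call, with an adjusted p from 0.0678 without the second wild type array at 24 h to 0.19 without the first wild type array at 0 h. The count was 109 with a trended and robust prior, 30 with damped low values, 9 with the filter at the 60th percentile and 3 with median centring. It was 0 without a filter, with array weights, with either replicate block and with only the 2 groups compared. Cyp2c55 (3.22, adjusted p = 0.0561), Prelid2 (below the filter limit in 1 group, 3.89, adjusted p = 0.0561), Tmem51 (1.71), Gys2 (-1.0), Fam178b (-2.49, below the filter limit in 3 groups) and Ntn4 (-1.25) were next by p. Tob2, Btg1, Btg2, Cnot7, Ccna2, Ccnd1 and Ccne1 did not pass. A further 6 lists passed with all 8 arrays at 24 h (adjusted p = 0.819 for each with an estimated correlation) and lost the call without single arrays. The values that follow leave out the first or second array of a genotype at 24 h. Immediate early genes (median -0.26 with all arrays) had -0.025 (adjusted p = 0.732) and -0.66 without the first and second wild type array, and -0.13 (adjusted p = 0.432) and -0.55 without the first and second null-labelled array. P450 genes (0.18) had 0.07, 0.34 and 0.28 without the first wild type, second wild type and second null-labelled array, and missed without the first null-labelled array (adjusted p = 0.0668). Cholesterol synthesis (0.32) had 0.04 (adjusted p = 0.76) and 0.74 without the wild type arrays, and 0.09 (adjusted p = 0.631) and 0.51 without the null-labelled arrays. Kupffer cell markers (0.28) had 0.13 (adjusted p = 0.102) and 0.52 without the wild type arrays, and 0.16 (adjusted p = 0.068) without the first null-labelled array. Fatty acid synthesis (-0.33) and glucose metabolism (-0.18) missed without the second wild type array (adjusted p = 0.0642 and 0.296) and without the second null-labelled one (-0.25, adjusted p = 0.265, and -0.09, adjusted p = 0.61). Without the first null-labelled array they had -0.525 and -0.28.

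**Figure D2:**
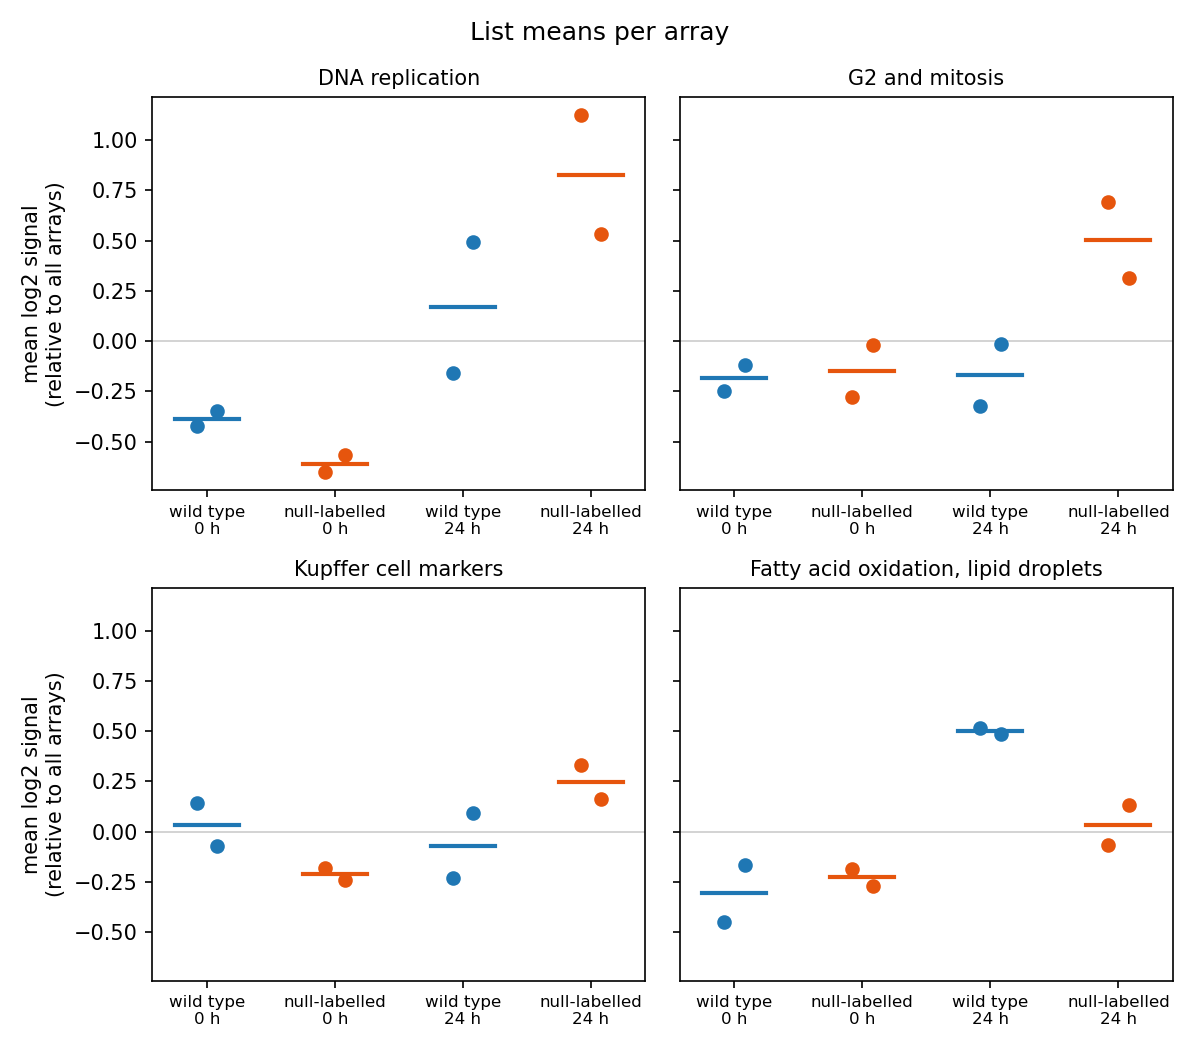
Mean log2 signal of a list's measured genes in each of the 8 arrays, relative to the mean over all arrays, for 4 lists (panels) with wild type in blue and null-labelled arrays in orange, 1 point per array (a pool of 3 animals) and a bar at each group's mean. For DNA replication the null-labelled arrays at 24 h stand at 1.12 and 0.53 and the wild type arrays at -0.16 and 0.50.

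The test of the difference between the responses asks whether a gene changed by another amount after hepatectomy in the null-labelled arrays than in wild type. DNA replication genes had the larger response in the null-labelled arrays, with a median difference of 0.87, and were on that side in 37 of 43 cases (camera adjusted p = 1.52e-07, adjusted p = 0.695 with an estimated correlation, adjusted p = 0.437 by fry). With the list averaged within each array, the difference was 0.88 ± 0.44 (SE between arrays). The camera p with the preset correlation compares the list with other genes and does not measure this spread between pools. Rrm2 stood at 1.53, Pcna at 1.16, Orc6 at 1.13 and Rfc4, of the clamp loader, at 2.11. The list median was 0.44 without the first null-labelled array at 24 h and still passed. G2 and mitosis genes had a median difference of 0.41 (adjusted p = 0.000199, adjusted p = 0.695 with an estimated correlation). Kif4 stood at 1.01 and Cdk1 at 2.14. The median was 0.28 (adjusted p = 0.0337) without the first null-labelled array at 24 h and 0.63 without the second array of either genotype at 24 h. Kupffer cell and macrophage markers moved the same way, in 16 of 18 cases with a median of 0.53 (adjusted p = 5.12e-06, adjusted p = 0.695 with an estimated correlation), among them Cd68 (1.52), Lyz2 (1.25) and Vsig4 (0.99). Fatty acid oxidation and lipid droplet genes went the other way in 24 of 30 cases, with a median of -0.28 (adjusted p = 6.32e-05, adjusted p = 0.695 with an estimated correlation), led by Cpt1a (-1.51). Cpt1a rose by 0.80 in wild type and fell by 0.71 in the null-labelled arrays. No single gene passed with limma, where the smallest adjusted p was 0.301 and 1244 genes had an unadjusted p under 0.05 against 722 by chance; 10 genes passed with a trended and robust prior. By p the leading genes with a positive difference (null-labelled minus wild type response) were Il21r (2.96), Gstm3 (2.05), Il22ra1 (2.84) and Cyp2c55 (2.54). Those with a negative difference were Dbp (-2.73), Pramel32 (-1.56), Cbx7 (-1.51) and Cpt1a. A negative difference need not be a smaller response: Dbp stood at -0.87 in wild type and at -3.60 in the null-labelled arrays. Il21r was below the filter limit in 2 groups and Il22ra1 and Cbx7 in 1. None of Tob1, Tob2, Btg1, Btg2, Cnot7, Ccna2, Ccnd1 and Ccne1 passed. The change of the 3' to 5' ratio after hepatectomy differed between the genotypes by -0.05 ± 0.20 (SE) for actin and -0.20 ± 0.12 for Gapdh.

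Averaged over both times, 5 genes passed between the null-labelled and the wild type arrays. Prelid2 (3.76 ± 0.22, below the filter limit in 1 group), Tmem51 (1.67 ± 0.12) and Gstm3 (1.55 ± 0.11) were higher, each with adjusted p = 0.0354, and Igfbp1 (-2.04 ± 0.13, adjusted p = 0.0354) and Cystm1 (-1.55 ± 0.13, adjusted p = 0.0495) were lower. The average for Gstm3 rests mostly on 24 h, as its values at that time and in the difference of responses show. In all, 1834 genes had an unadjusted p under 0.05, where 722 would by chance. The null-labelled arrays had the higher 3' to 5' ratio at both times (actin 1.57 against 1.22 and 1.27 against 0.97). Interferon response genes were higher in 21 of 24 cases (0.38, adjusted p = 1.24e-06, adjusted p = 0.907 with an estimated correlation), and 9 passed adjusted over the list alone, with Usp18 at 1.04 and Irf7 at 1.20. G2 and mitosis genes were higher (0.26, adjusted p = 0.000114, adjusted p = 0.907 with an estimated correlation) in 31 of 43 cases, among them Cks1b (0.93). Fatty acid oxidation genes were lower (-0.20, adjusted p = 0.000114, adjusted p = 0.907 with an estimated correlation) in 26 of 30. Without the first or the second wild type array at 24 h 1 gene was called, Prelid2 both times, and without any of the other arrays none was. The count was 130 with a trended and robust prior, 36 with damped low values, 32 with the filter at the 60th percentile, 10 with median centring and 9 on the deposited values, each including at least 4 of the 5. It was 0 without a filter and with either replicate block. The DNA replication list passed with all arrays (0.23, adjusted p = 0.00754, adjusted p = 0.907 with an estimated correlation). It missed without the first wild type (0.04, adjusted p = 0.308) or the first null-labelled array at 24 h (0.09, adjusted p = 0.471), and its median was 0.41 and 0.43 without the second array of either genotype at 24 h and 0.145 without the first wild type array at 0 h. A further 6 lists likewise lost the call without at least 1 array, namely P450, endothelial, ER chaperone, fatty acid synthesis, female-biased and G1 to S genes. The female-biased median was 0.25 without the first null-labelled array at 0 h, which stood apart by these genes, and 1.18 without the second.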

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

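The comparison with the macrophage list was chosen after the result was seen. The other tests of this part were set before, but their bounds did not include the margin of an SD used below.

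A total of 10 gene lists had a hepatectomy response that differed between the null-labelled and the wild type arrays by camera with the preset correlation, none of them with an estimated correlation (smallest adjusted p = 0.695). The medians of this difference were 0.87 for DNA replication (adjusted p = 1.52e-07), 0.41 for G2 and mitosis (adjusted p = 0.000199), 0.53 for Kupffer cell and macrophage markers (adjusted p = 5.12e-06) and -0.28 for fatty acid oxidation (adjusted p = 6.32e-05). These 4 kept the call whichever array was left out. Without the first null-labelled array at 24 h the medians fell to 0.44 for DNA replication and 0.28 for G2 and mitosis. For G2 and mitosis the median was 0.63 without the second array of either genotype at 24 h. Cholesterol synthesis had a median of 0.61 (adjusted p = 0.000199), with 0.25 (adjusted p = 0.0547) without the first and 0.96 without the second wild type array at 24 h. P450 genes had 0.10 (adjusted p = 0.0365) and missed without the second wild type (adjusted p = 0.116) or either null-labelled array at 0 h (0.0745 and 0.0924) and without the first wild type (median 0.06, adjusted p = 0.326) or null-labelled (median 0.02, adjusted p = 0.325) array at 24 h. Without the second ones its median was 0.18 and 0.20. Fatty acid synthesis had -0.35 (adjusted p = 0.0365) and missed without the first wild type (0.0667) or null-labelled (median -0.21, adjusted p = 0.312) array at 0 h and the second wild type (0.141) or null-labelled (median -0.11, adjusted p = 0.386) array at 24 h. It had -0.55 without the first null-labelled array at 24 h. ER chaperones had -0.12 (adjusted p = 0.0322) and missed without the second wild type (0.0562) or the first null-labelled (0.136) array at 0 h and the second wild type (0.141) or null-labelled (median -0.06, adjusted p = 0.588) array at 24 h. They had -0.22 without the second null-labelled array at 0 h and -0.33 without the first at 24 h. With median centring their median turned to 0.02 (adjusted p = 0.0534). Ribosome biogenesis had -0.28 (adjusted p = 0.0313) and missed without the first array of any group (0.172 and 0.915 in wild type, 0.164 and 0.612 in the null-labelled arrays, at 0 h and 24 h). Its median was -0.046 without the first and -0.51 without the second wild type array at 24 h, and -0.053 without the first null-labelled one. Endothelial markers had 0.31 (adjusted p = 0.0109) and missed without the first wild type (0.0703) or null-labelled (0.137) array at 0 h and the second null-labelled array at 24 h (0.0739).

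The larger rise of DNA replication genes in the null-labelled arrays was not made by the quantile normalisation, as its median was 0.824 on the deposited values. With median centring its median was 0.94, where the median of all genes was 0.12. The deposited arrays appear to have been scaled already, and that scaling was not tested. Whether a single array decides the larger rise is left open. Without the first null-labelled array at 24 h the median was 0.44, just above 0.437, the bound set before. By that bound alone a single array would not decide it. The SD over the arrays left out was 0.26, far more than the distance to the bound. A larger share of macrophages may contribute and stays open too, since the DNA replication list exceeded the Kupffer cell list by only 0.32 ± 0.31 (SE). The mean differences of the lists themselves were 0.88 ± 0.44 and 0.56 ± 0.21 (SE between arrays). Relative to all arrays, the Kupffer cell list stood at -0.18 and -0.24 in the null-labelled and 0.14 and -0.07 in the wild type arrays at 0 h. At 24 h the values were 0.33 and 0.16 against -0.23 and 0.09. The difference of responses of this list thus came partly from lower values in the null-labelled arrays at 0 h. The absence of Tob1 is the biological explanation that the design names, and it is untested apart from the labels.

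Among 5008 probe sets without a single gene name, which the comparisons do not use, 3 were higher and 4 lower at 24 h in wild type, and 12 were higher and 1 lower in the null-labelled arrays.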

How the results depend on the processing

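Damped low values and the crossed block were chosen after the data were seen; the planned pseudocounts 1 and 64 were not run because the values were already log2. The cause of a change was not tested except where fewer genes or arrays show it. Counts are in the order wild type response, null-labelled response, genotypes at 0 h, at 24 h, and averaged, where they left the range of 1.5 times. With the deposited values 3 genes were called at 0 h and 9 on average. Median centring gave 806 in wild type, 2, 3 and 10 in the genotype comparisons and 523 shared between the responses; the median of all genes was then 0.12 in the null-labelled response and in the difference of responses and 0.14 between genotypes at 24 h (-0.035, 0.000 and 0.006 with quantile normalisation). Without a filter the counts were 542, 1026, 1, 0 and 0, with 333 shared and r = 0.508. At the 60th percentile they were 2346 in wild type, then 8, 9 and 32, with 1561 shared and r = 0.775. The trended and robust prior gave 2592, 3204, 13, 109 and 130, with 10 for the difference of responses and 1700 shared. Array weights gave 5 at 0 h and 0 at 24 h. The replicate block gave 332 and 903, 0 at 24 h and 0 on average, with 238 shared, although equal numbers do not pair arrays (correlations of deviations from -0.197 to 0.051). Only the 2 groups compared gave 2, 0 and, at 24 h, 0. Damped values gave 2170, 7, 30 and 36 (wild type and the genotype comparisons), with 1406 shared; the crossed block gave 0 at 24 h and 0 on average. At an adjusted p under 0.01 the counts were 16, 51, 0 (24 h) and 0 (average). Leaving out each array gave 3 to 1446 genes in wild type, 30 to 1804 in the null-labelled arrays, 0 to 1 at 24 h, 0 to 1 on average and 3 to 674 shared, with r from 0.578 to 0.664.

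The DNA replication list kept its direction throughout. With all arrays its medians were 0.61, 1.52, 0.68, 0.87 and 0.23 (wild type response, null-labelled response, 24 h, difference of responses, average), and its call ended in each with an estimated correlation (adjusted p = 0.677, 0.445, 0.819, 0.695 and 0.907) and, except in the null-labelled response, with fry (adjusted p = 0.289, 0.376, 0.437 and 0.642). Leaving out each array its medians ran from 0.36 to 0.69, 1.08 to 1.84, 0.28 to 1.07, 0.44 to 1.19 and 0.04 to 0.43. The mean of its probe sets turned Tob1 to -0.34 at 0 h and -0.36 at 24 h, as its 2 probe sets differ in direction. Cholesterol synthesis genes at 24 h turned direction by camera without the first wild type array at 24 h; leaving out each array gave medians from 0.043 to 0.739. Of 208 further values that the naming rule covers and the text does not print, 26 changed direction in some setting, 2 of them called with all arrays (Pa2g4 and Psmd13 in the null-labelled response, with the mean of probe sets). Low signals limit folds: a mean below 3.60 is imprecise.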

Other observations

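The tests with female-biased genes and with the 100 genes nearest to Tob1 were chosen after the results were seen; the other tests of this part were set before.

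The circadian clock list did not pass after hepatectomy in either genotype, with a median of 0.03 in wild type (adjusted p = 0.974) and -0.26 in the null-labelled arrays (adjusted p = 0.441). Of its 17 measured genes, 1 rose and 3 fell in wild type (3 and 4 adjusted over the list alone), and 3 rose and 4 fell in the null-labelled arrays (4 and 4 adjusted over the list alone). Nr1d1 fell by 2.92 in wild type (adjusted p = 0.0158) and by 3.92 in the null-labelled arrays (adjusted p = 0.00873). Dbp stood at -0.87 (adjusted p = 0.057) and -3.60 (adjusted p = 0.006), and Per2 at 2.12 (adjusted p = 0.0199) and 1.44 (adjusted p = 0.0308). The time of day of tissue collection is not given in the sources used here.

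Dbp and Ciart were the clock genes with the largest values at 0 h in the null-labelled arrays (2.15, adjusted p = 0.125, and 2.35, adjusted p = 0.162, Ciart below the filter limit in 1 group), neither past the threshold. Another clock phase at tissue collection is a candidate explanation. A score took 7 other genes, set in advance as in phase with Dbp, minus 5 set as in antiphase. The score was higher by 0.73 ± 0.28 (SE) at 0 h in the null-labelled arrays, with a difference of -0.11 at 24 h. Nr1d1 (0.98) and Arntl (-1.05) went that way, while Tef (-0.22), Hlf (-0.12) and Per3 (-0.32) did not. Per2, set as in phase, was higher after hepatectomy (2.12 in wild type, 1.44 in the null-labelled arrays), where Dbp was lower (-0.87 and -3.60). The score is therefore only an approximate measure of phase. A biological effect of the genotype on the clock stays open and untested.

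The first null-labelled array at 0 h had a high signal of Xist, the RNA that silences an X chromosome in females, at 7.94 against 3.00 to 4.48 in the other 7 arrays, although the animals are described as male. Of 2 further Xist probe sets, 1 was higher in this array by over 1 (3.05 above every other array) and the other by 0.08, which argues against noise of 1 probe set; the bound written in advance asked for 2, which was too strict, as only these 2 exist. RNA of female animals in the pool may explain it: the female-biased list lay 1.86 above the other array of the group on average, and the mean score of 3 Y-linked genes was lowest in this array (-0.57). Of the 13 female-biased genes 9 were higher than in that other array, 7 of them by over 1 (Sult3a1 at 9.24 against 3.47). Cyp3a44, Fmo2 and Abcd2 were lower, and Cux2 was equal to 2 decimals. Of the Y-linked genes, Kdm5d was not lowest there (5.76, against 5.53 in the second null-labelled and 5.66 in the second wild type array at 24 h). The mean female-biased score was also higher in the null-labelled arrays at 24 h (0.52 and 0.12) than in every wild type array (-0.66 to -0.23). Xist was 4.30 and 4.48 in these null-labelled arrays, and Sult3a1 was high in the first of them (7.08). The female-biased list is thus raised there without a high Xist signal. No biological explanation was tested.

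For the 5 genes called on average between genotypes, 2 of the 35 splits of the 8 arrays into 4 and 4 called as many, the other being the split by time with 3755 genes. Time is the other factor of the design and a structure of the samples, so its split was bound to call as many and kept the share above 0.05; the count therefore leaves chance open, and every remaining split called 0. DNA of another strain carried along with the null allele could give such differences, and 1 of the 5, Igfbp1, lies on the chromosome of Tob1, as do 1172 of 14422 genes. Of the 100 genes nearest to Tob1 6% had an unadjusted p under 0.01, against 3.69% of all (two-sided Fisher's exact p = 0.187), which leaves this open. Of the other called genes, Prelid2 and Cystm1 both lie on chromosome 18, Gstm3 on 3 and Tmem51 on 4. DNA of another strain away from Tob1 was not tested.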
